A study of Drosophila melanogaster with 2 samples.

How the data were processed

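The data are ChIP-seq peak lists from 2 biological replicates of whole Drosophila melanogaster embryos aged 0 to 16 h, from a line with GFP fused to CG3065, precipitated with an anti-GFP antibody. Chromatin was sonicated to 200 to 800 bp, per the labels. The labels do not say whether the replicates came from separate embryo collections beyond calling them biological replicates. They were numbered 1 and 3.

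The deposited lists are in narrowPeak format in the builds dm6 and dm3. For each build there is a relaxed list per replicate and 1 from both replicates pooled, made as input to IDR, and 1 list of IDR-thresholded peaks drawn from them, per the file records. The authors named the pooled relaxed lists as peaks and background. In the dm6 one the -log10 q went down to 0.0314, so an entry need not mark binding. The signal per peak is the authors' value as their caller gave it, used to rank and describe peaks within a list. The deposited -log10 q per peak reaches a common maximum in 88.1% of the dm6 IDR peaks, so it cannot rank them. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. Control libraries were not analysed here. The files hold no read counts, so depth is unknown. The 2451 dm6 IDR peaks are exactly the pooled relaxed peaks of highest signal, so the choice between these sources changes no value. Intervals are Clopper-Pearson at 95%; for the chemoreceptor and cuticle lists, with a count of 0, the share of 3 counts is also given. Both cover counting error only.

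Positions were compared with the Ensembl release 115 annotation (BDGP6 version 54) and the sequence of Release 6, which dm6 shares. All relaxed peaks ended within the chromosome lengths, and 13944 of 13945 protein-coding genes had the same start and end in the RefSeq annotation. Coordinates are 1-based dm6 and none was converted between builds. Each summit took the first class that applied, from promoter (within 500 bp of a protein-coding start site) through 5' untranslated region, coding exon, 3' untranslated region and other exon to intron and intergenic. The background was the 27067 pooled relaxed peaks that overlap no IDR peak.

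Odds ratios had 0.5 added to each cell. Replicate overlap was compared with 1000 circular shifts per arm, and medians with 100000 permutations and 2000 bootstrap draws. Motif windows reached 50 bp either side of the summit, with a control window centred 500 bp to the right. Motifs and 7-base words, each merged with its reverse complement, were compared by the exact McNemar test. All families of tests were adjusted by Benjamini-Hochberg. Peaks and genes were the units, so p-values carry no spread between samples. Gene lists were matched by symbol; 4 symbols were not matched and are not reported here, and 2 were matched by synonym. The tRNA list was compared with all annotated genes.

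Tests, gene lists, motifs, most alternatives and the rule for named genes were fixed before the data were examined. The alternatives that count each summit for its nearest start site only, that leave out genes of another kind from the histone, cuticle and chorion lists, and that compare classes outside promoters only, were added afterwards. Named are the 25 IDR peaks of highest signal by nearest start site, up to 4 members per list past the threshold, all Sp/KLF and Hox genes, and the 5 genes with most IDR peaks within 5 kb. Of the words, the 10 higher and 5 lower with the smallest p are named. The members named for lists that did not pass, Cpr, and the other words of the Sp/KLF box, were chosen after their values were seen. Alternatives left out each replicate in turn (the strongest relaxed peaks of the other in place of the IDR set) and changed the threshold, windows, background, control and test.

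The procedures were tested on simulated data. All 80 planted gene lists of 60 genes with peaks at 40% of genes were recovered (100%), with 0.833% false calls among 480 null lists. Many real lists are smaller, such as those of 8 Hox and 12 glycolysis genes, so this recovery does not carry over to them. Simulated peaks were drawn for each gene independently, so the rate of false calls does not cover summits shared by neighbouring genes. For lists drawn from genes with many start sites, where the chance of a peak was made to rise with their number, Fisher's exact test called 68.0% of 200 null lists and the logistic regression 3.5%. The list test therefore does not separate a list from the number of start sites of its genes. Planted words in 5% of windows were recovered in 20 of 20 cases, and windows to the right against those to the left gave 0% calls among 8192 words. These windows were alike in GC content (43.0% and 43.4%). The 0% therefore does not cover calls that follow from the lower GC content of summits (36.8%).

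Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.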

Results

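Binding of CG3065, a zinc finger protein of the Sp/KLF family, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster. The fly line carried a fusion of CG3065 to green fluorescent protein (GFP) at its C-terminus, and chromatin from whole mixed-sex embryos aged 0 to 16 h was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, numbered 1 and 3 in the labels, so nothing was compared between groups of samples. In dm6 coordinates, the relaxed peak lists held 30000 peaks for replicate 1, 26271 for replicate 3 and 30000 for the pooled reads. The pooled relaxed list was named by the authors as peaks and background, so a relaxed peak need not mark binding. A thresholded list of 2451 peaks, chosen by the authors with the irreproducible discovery rate (IDR), is called the IDR peaks here. The lists give no read counts, so the sequencing depth of each replicate is unknown.

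The first question was how far the replicates shared their strongest peaks. Of the 2451 relaxed peaks of highest signal in replicate 1, 1765 were overlapped by at least 1 bp by one of the 2451 highest of replicate 3. That is 72.0% (95% Clopper-Pearson interval 70.2% to 73.8%). Circular shifts of the replicate 3 peaks along each chromosome arm gave a mean of 1.34% and at most 2.41% in 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). A relaxed peak within 200 bp of the summit was found in both replicates for 2431 of the IDR peaks. Across these peaks Spearman's rho of signal between replicates was 0.569. It was 0.341 across 9549 matched relaxed peaks outside the IDR set, and 0.612 across all 12315 matched pooled relaxed peaks. The IDR peaks are the pooled relaxed peaks of highest signal, so their matches and their rho depend on that cut. Peaks are not independent replicates, and no p-value is attached to any rho.

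**Figure D1:**
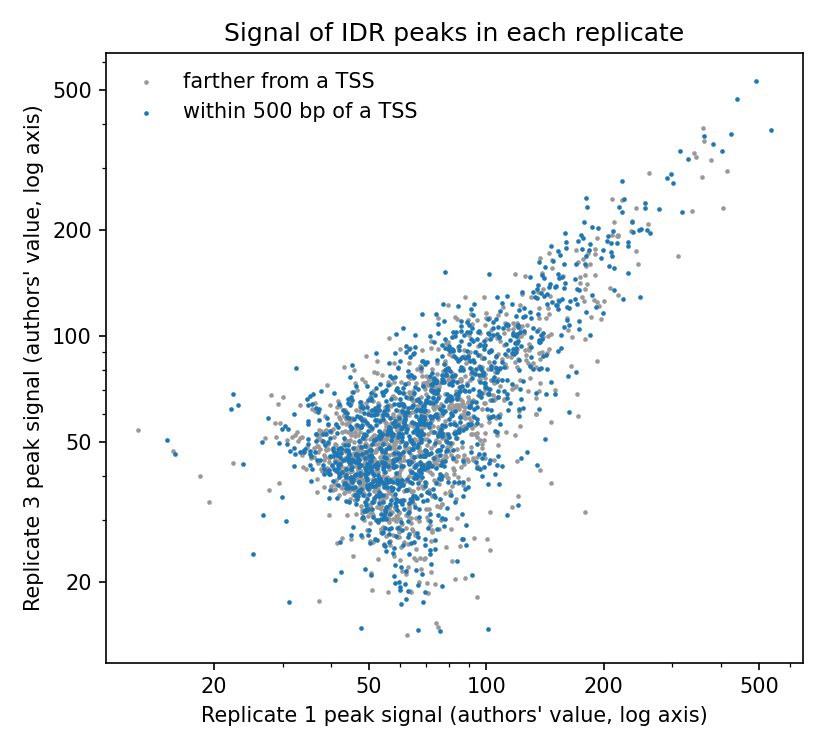
Signal of each IDR peak in replicate 1 (horizontal) and replicate 3 (vertical), both the authors' values without unit on log axes, for the 2431 IDR peaks with a relaxed peak in both. Blue points lie within 500 bp of a protein-coding transcription start site and grey points farther away; Spearman's rho across peaks was 0.569.

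The strongest IDR peak lay near the start of CG14100 on 3L (19590458 to 19590801, dm6), with a signal of 1017 in the pooled list. It ranked 2 in replicate 1 and 1 in replicate 3. The next were promoter peaks of px, a gene of wing vein patterning, on 2R (22514142 to 22514468, signal 912), of Ugalt, a UDP-galactose transporter, on X (2703729 to 2704054, signal 906), and of Sox14, an HMG-box transcription factor, on 2R (23978414 to 23978689, signal 814). The peak of rank 5 had a signal of 752 and lay on 2L (480927 to 481251), in an intron, within ush and outside cbt. The nearest start site, 1397 bp away, was that of cbt, another member of the Sp/KLF family. CG1888, the chromatin protein gene Chro and the arginine methyltransferase gene Art3 had promoter peaks with signals of 736, 733 and 733. A peak in a coding exon, 7086 bp from the start of the RNA-binding protein gene fus, had a signal of 716.

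Of the 25 strongest IDR peaks, 15 lay at promoters, 7 in introns, 1 between genes and 2 in exons. Further promoter peaks among them were those of CenG1A (signal 650), ph-p (644), mRpL41 (583), Tcs5 (578), PNPase (566), CG31523 (549), gish (513) and CG8320 (497). The intronic peaks included those nearest to CG11050 (699), CG9663 (681), the kinase gene Lk6 (673), COX7AL2 (635) and HmgZ (548). A peak with a signal of 641 had the start of abd-A, a Hox gene, as its nearest, 17393 bp away. It lay outside abd-A, in an intron of another gene. The peak nearest to hll (553) lay in another exon and the one nearest to CG13323 (691) between genes. All 25 had a peak in both replicates, with ranks down to 47 in replicate 1 and 35 in replicate 3. Their choice by pooled signal favours this. A gene is named here for its nearest start site, which does not show that the peak lies in it or acts on it.

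IDR peaks lay at promoters more often than the weaker entries of the pooled relaxed list did. Of 2451 IDR summits, 1236 were within 500 bp of the start site of a protein-coding gene, or 50.4% (48.4% to 52.4%). Among 27067 other relaxed peaks of the pooled list the share was 22.5% (21.97% to 22.97%). The log2 odds ratio was 1.81 (Fisher's exact test, two-sided, p = 1.09e-180). The median distance to a start site was 470 bp for IDR peaks and 2412 bp for the others.

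Coding exons and 3' untranslated regions were less frequent among IDR peaks. Coding exons held 0.816% of IDR summits against 6.25% of the others (adjusted p = 2.26e-40), and 3' untranslated regions 0.979% against 3.69% (exact test, adjusted p = 9.27e-16). Introns held 30.6% against 41.3% (adjusted p = 1.97e-25), and the space between genes 14.9% against 23.2% (exact test, adjusted p = 2.33e-22). Since the shares add up to 100%, a higher promoter share lowers the rest. Among the 1215 IDR and 20985 other summits outside promoters, introns were higher (61.6% against 53.2%, adjusted p = 3.17e-08) and the space between genes did not pass (30.1% against 29.9%, exact test, adjusted p = 0.897). Coding exons (1.65% against 8.06%, adjusted p = 5.25e-21) and 3' untranslated regions (1.98% against 4.76%, exact test, adjusted p = 1.93e-06) were still lower. The 5' untranslated regions (0.571% against 0.961%, adjusted p = 0.0705) and other exons (1.71% against 2.14%, adjusted p = 0.185) did not pass the exact test over all summits. The 5' untranslated regions passed as lower in the stronger part of the IDR set (adjusted p = 0.0247) and with a promoter window of 1000 bp (exact tests, adjusted p = 0.016), and the direction for other exons was not stable across alternatives. These are Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the 7 classes of the location table, or over those other than promoter for summits outside promoters. They treat peaks as independent and carry no spread between embryos.

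**Figure D2:**
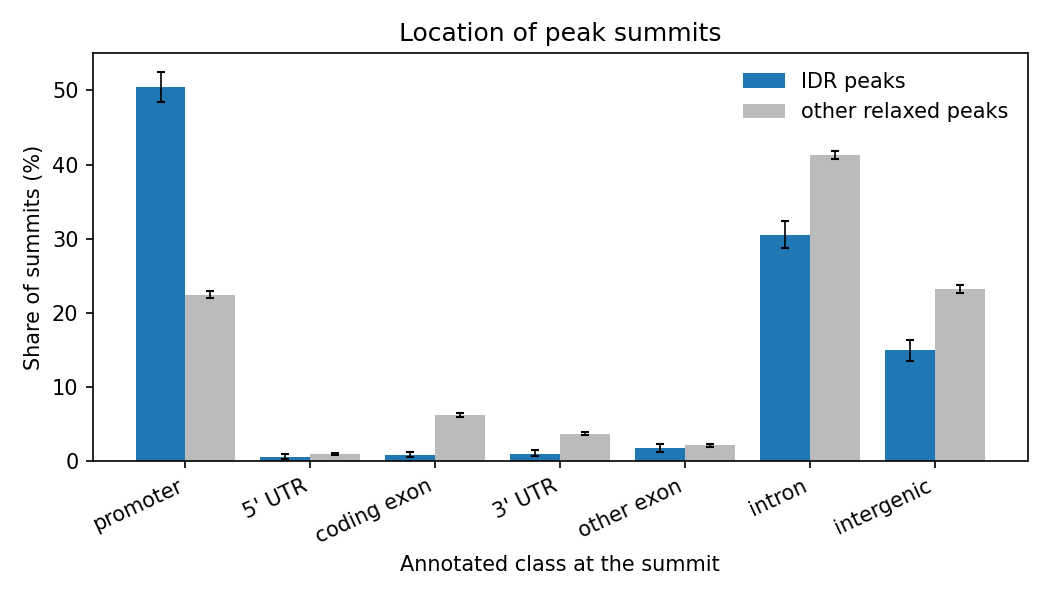
Share of summits (%) in each annotated class for the 2451 IDR peaks (blue) and 27067 other relaxed peaks of the pooled list (grey), with 95% Clopper-Pearson intervals as error bars. The promoter class held 50.4% of IDR summits and 22.5% of the others.

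Promoter peaks were also slightly stronger than the rest of the IDR set. The median signal was 120 over 1236 promoter peaks and 111 over 1215 others, a difference of 9.57 (95% bootstrap interval 5.26 to 13.2; two-sided permutation test, p = 4.0e-05). In the strongest peaks of replicate 1 alone, without replicate 3, the medians were 66.7 and 64.3 on that list's own scale, and the difference did not pass (permutation p = 0.0624).

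Genes on the X chromosome carried promoter peaks less often than autosomal genes. An IDR summit lay within 500 bp of a start site in 201 of 2196 X-linked protein-coding genes, or 9.15% (7.98% to 10.4%), and in 1472 of 11669 genes on the large autosomal arms, or 12.6%. The log2 odds ratio was -0.52 (Fisher's exact test, two-sided, adjusted p = 5.63e-06). The IDR set is a cut by signal. Without control libraries, these shares were not corrected for the dose of X-linked DNA in mixed-sex embryos. On chromosome 4 the share was 5 of 80 genes, or 6.25% (2.06% to 13.99%), and did not pass (Fisher's exact test, adjusted p = 0.0915). By length, the density of IDR peaks was 17.3 per Mb on X, between 16.9 on 2R and 20.6 on 2L among the large autosomal arms, and 14.1 on chromosome 4. Neither IDR nor relaxed peaks were listed on Y.

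Genes of the cytosolic ribosome stood out among 28 gene lists. In all, 1678 of 13945 protein-coding genes (12.03%) had an IDR summit within 500 bp of a start site, and a summit could count for several neighbouring genes. Among cytosolic ribosomal protein genes it was 46 of 93, or 49.5% (38.9% to 60.03%; log2 odds ratio 2.87, Fisher's exact test, adjusted p = 2.11e-17). The highest were RpS27 on 3R (summit 25247520, signal 381), RpL7 on 2L (10201048, signal 358), RpL23A on 3L (1668734, signal 281) and RpLP0 on 3L (22076060, signal 225). Mitochondrial ribosomal protein genes had peaks in 16 of 73 (21.9%, adjusted p = 0.0595), oxidative phosphorylation genes in 12 of 84 (14.3%, adjusted p = 0.585) and proteasome genes in 3 of 48 (6.25%, adjusted p = 0.395), none past the threshold of the exact test. With a narrower promoter window mitochondrial ribosomal protein genes just passed (14 of 73, exact test, adjusted p = 0.0499).

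Glycolysis genes and genes of the Polycomb and trithorax groups were also higher. Peaks were found at 6 of 12 glycolysis genes (exact test, adjusted p = 0.0068), among them Gapdh2 (signal 231), Ldh (216), Eno (214) and Pgk (139). They were found at 8 of 22 Polycomb and trithorax genes (36.4%, exact test, adjusted p = 0.0116), with the highest at ph-p (644), brm (270), E(z) (212) and Sfmbt (155). In a logistic regression that took the number of start sites and gene length into account, both narrowly missed the threshold, with log2 odds ratios of 2.11 for glycolysis (2.874 in the main test; an adjusted p of 0.0569) and 1.75 for the Polycomb and trithorax list (2.10 in the main test; an adjusted p of 0.0504). With each summit counted only for its nearest start site both passed, at log2 odds ratios of 3.45 and 2.68 (exact tests, adjusted p = 0.00174 each). The Polycomb and trithorax list also missed the threshold in the strongest peaks of replicate 3 alone (exact test, adjusted p = 0.131) and in the stronger part of the IDR set (exact test, adjusted p = 0.206). In the same regression mitochondrial ribosomal protein genes passed, with an adjusted p of 0.00497. With summits counted for the nearest start site, however, 7 of these 73 genes had a peak (9.59%, against 8.41% of other genes; exact test, adjusted p = 0.817).

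Several lists of genes had few or no promoter peaks. None of 179 chemoreceptor genes had one (adjusted p = 2.16e-09), with a Clopper-Pearson upper limit of 2.04% (1.68% by the limit of 3 counts), and none of 96 genes matched as cuticle proteins (exact tests, adjusted p = 8.78e-05, upper limit 3.77%, or 3.13% by 3 counts). The pattern for the latter also took Cpr, which encodes a cytochrome P450 reductase; without it there were 0 of 95 (exact test, adjusted p = 6.28e-05, upper limit 3.81%). Of 115 genes matched as histones, 2 had one (1.74%, exact test, adjusted p = 0.000867). These were His3.3B (signal 178) and His2Av (115), which encode variant histones made outside replication although the list was meant for replication-dependent genes. Without 4 such variants there were 0 of 111 (exact test, adjusted p = 1.01e-05, upper limit 3.27%). These 111 are copies of the repeated cluster on 2L, and 0 had even a relaxed peak, so 0 IDR peaks was fixed. Repeated copies are not independent genes, so neither histone test nor the limit measures a lack of binding. Of 290 tRNA genes 13 had a peak, or 4.48%, against 10.2% of all other genes (exact test, adjusted p = 0.00417). That difference did not pass with a window of 1000 bp (11.03% against 12.4%, exact test, adjusted p = 0.594) or in the logistic regression, where the log2 odds ratio was 0.07 with an adjusted p of 0.897.

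Lists of developmental genes did not pass at promoters. Peaks were found at 1 of 26 segmentation genes (nkd, signal 162), 3 of 20 dorsoventral and mesoderm genes (tin, tld and htl), 2 of 26 neural progenitor genes (elav, signal 286, and pros, 98.7), 1 of 12 hemocyte genes (ush, 194) and 1 of 20 genes of trachea and epidermis (trh, 91.6). They were found at 4 of 18 Notch pathway genes, 3 of 13 Hippo pathway genes, 5 of 23 muscle genes, 2 of 9 gut genes, 4 of 14 germline genes and 6 of 32 genes of cell cycle and replication. When summits anywhere in a gene or up to 1000 bp upstream were counted, 3 of these lists passed as higher, dorsoventral and mesoderm (adjusted p = 0.00987), Hippo pathway (adjusted p = 0.0323) and Notch pathway (exact tests, adjusted p = 0.0435), in a test that takes no account of gene length. The lists for heat shock (4 of 15), circadian rhythm (4 of 10, adjusted p = 0.075), chorion and accessory gland (2 of 58), digestive proteases (0 of 27, upper limit 12.8%) and neuronal differentiation (0 of 17, upper limit 19.5%) did not pass the main exact test either. Counted over the whole gene, digestive proteases (adjusted p = 0.0401) and the chorion and accessory gland list (exact tests, adjusted p = 0.0138) passed as lower. By nearest start site the latter passed as lower (adjusted p = 0.0444) and circadian rhythm as higher (exact tests, adjusted p = 0.0243). In the strongest peaks of replicate 1 alone the chorion and accessory gland list passed as well (exact test, adjusted p = 0.0282). In the logistic regression neuronal differentiation passed as lower, with an adjusted p of 0.0122. The chorion and accessory gland list holds 4 genes of another kind, and 1 of its peaks is that of Cp190, an insulator protein gene (signal 295); without them there was 1 of 54 (exact test, adjusted p = 0.0572). All list tests other than the logistic regression were two-sided Fisher's exact tests, and each set was adjusted by Benjamini-Hochberg over the 28 lists.

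**Figure D3:**
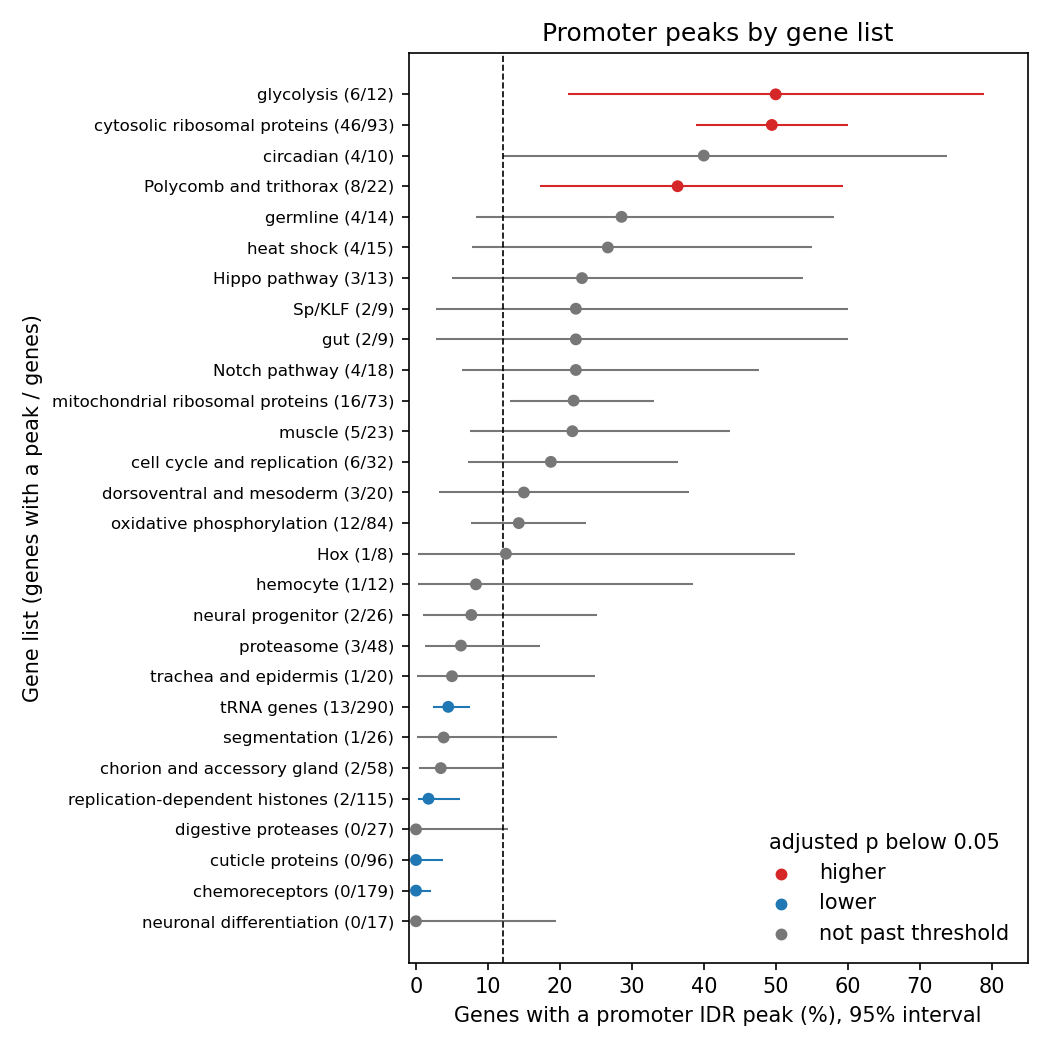
Share of genes (%) with an IDR summit within 500 bp of a start site, for each of the 28 gene lists, with 95% Clopper-Pearson intervals and the counts beside each name. Red lists were higher and blue lists lower than all other genes at an adjusted p below 0.05 in Fisher's exact test; the dashed line marks the 12.03% of all protein-coding genes.

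Of the 8 Hox genes, which set segment identity, only lab had an IDR summit within 500 bp of a start site (3R, 6678710, signal 121). Within 5 kb of the gene, Antp had 5 IDR peaks (highest signal 107), Abd-B had 2 (highest 223) and Ubx had 1 (140), while pb, Dfd, Scr and abd-A had 0. The list did not pass (exact test, adjusted p = 1).

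The gene of the tagged protein, CG3065 (2R, 23970305 to 23972233), had an IDR summit at its start site with a signal of 114. Of the other Sp/KLF genes, cbt also had a promoter peak (signal 277). Within 5 kb of the gene, 3 IDR peaks lay at dar1, 2 at Spps and 1 at luna, and 0 at btd, Sp1, Klf15 and CG42741. With 2 of 9 genes at a promoter, the list did not pass (exact test, adjusted p = 0.395). The longest runs of IDR peaks within 5 kb of a gene were 12 at CG1677 and 10 at Raf, a kinase gene. Next came 9 at ush, a cofactor of GATA factors, among them the peak of rank 5, and 8 each at sbb and tara. The counts were not adjusted for gene length, and CG1677 spans 7281089 to 7405797 on X. No IDR summit lay within 500 bp of a start site of CG1677 or tara.

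The box bound by Sp/KLF factors was found at IDR summits more often than beside them. The pattern CMCRCCC occurred within 50 bp of 11.3% of summits (10.04% to 12.6%) and in 4.90% of windows centred 500 bp to the right (exact McNemar test, two-sided, adjusted p = 9.37e-15). The core promoter element DRE was also higher (1.80% against 0.367%, adjusted p = 7.94e-06), as was the CTCF core (6.41% against 3.67%, exact test, adjusted p = 4.27e-05). Motif 1, the site of M1BP, was at 0.775% against 0.204% (adjusted p = 0.0123), Ohler motif 6 at 3.55% against 2.16% (adjusted p = 0.0104) and the TATA box at 5.67% against 3.79% (exact test, adjusted p = 0.00728). The CA repeat was lower, at 1.88% against 3.998% (exact test, adjusted p = 4.27e-05). The GAGA factor, Zelda, Pho, Initiator and both E-box patterns did not pass among the 13 motifs. In the strongest peaks of replicate 3 alone, the GAGA factor (adjusted p = 0.000567) and Pho (adjusted p = 0.00287) passed as lower and motif 1 did not pass (exact test, adjusted p = 0.101). In those of replicate 1 alone every motif kept its side of the threshold. With the control window to the left, the GAGA factor (adjusted p = 0.0267), Zelda (adjusted p = 0.0271) and the Twist-type E-box (adjusted p = 0.0492) passed as lower and Ohler motif 6 did not pass (exact tests, adjusted p = 0.134). With windows of 100 bp either side Pho passed as lower (exact test, adjusted p = 0.00155). The direction of these was not stable, since the log2 ratio of Pho was 0.241 with the left control, and with GC-matched summits as control the log2 odds ratio was 0.17 for Pho and 0.576 for the GAGA factor, none past the threshold. In the stronger part of the IDR set, with fewer peaks, DRE (log2 ratio 1.51 against 2.23, adjusted p = 0.0736), motif 1 (1.14 against 1.83), Ohler motif 6 (0.675 against 0.72) and the TATA box (0.56 against 0.588) did not pass the exact test.

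Summit windows had less G and C than their surroundings, at 36.8% against 43.0% to the right. With other relaxed summits of the same GC content as control, 3 of the 7 calls remained past the threshold, those of the Sp/KLF box (11.3% against 7.02%), DRE (1.81% against 1.07%) and the CTCF core (6.45% against 3.63%).

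Among all 8192 words of 7 bases, CACGCCC had the smallest p. It occurred at 232 summits (9.47%) and in 33 control windows (1.35%; exact McNemar test, two-sided, adjusted p = 1.87e-34). The overlapping words CCACGCC (8.45% against 1.39%), GCCACGC (7.67% against 1.22%) and ACGCCCC (4.98% against 0.857%) were also among the 10 leading words. The other 6 were made of A and T, such as TTAAAAA (14.4% against 6.36%) and ATTTTAA (11.9% against 4.73%). Words that were lower at summits were led by CAACAAC (1.88% against 5.34%) and CACACAC (2.86% against 6.49%), followed by CTCCTCC, CCTCCTC and CCAGCTC. In all, 362 words were higher and 354 lower. Apart from CACGCCC, single words were not compared at equal GC content. Of the other words of the box, CCCGCCC (1.67% against 1.10%), CACACCC (0.857% against 1.39%) and CCCACCC (0.612% against 1.22%) did not pass. Of the 25 strongest peaks, 5 had CACGCCC within 50 bp of the summit.

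**Figure D4:**
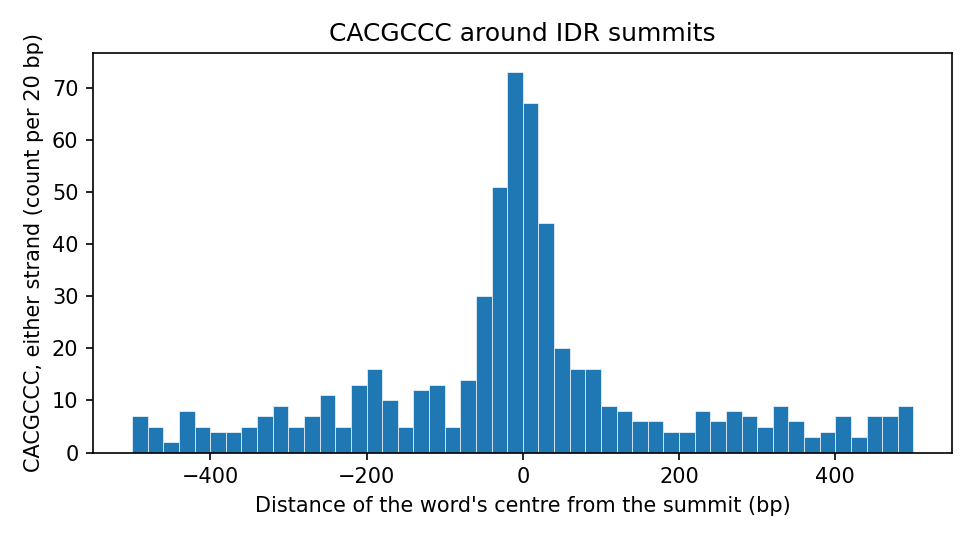
Number of CACGCCC words on either strand (vertical) by distance of the word's centre from the IDR summit in bp (horizontal), in steps of 20 bp over all 2451 IDR peaks. The 2 steps beside the summit hold 73 and 67 words.

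The authors' lists from the same reads held 2451 IDR peaks in dm6 and 2198 in dm3, an excess of 253 or 11.5% in dm6. On X there were 407 and 357, on 3L 528 and 463, and on chromosome 4 19 and 18. In each build the IDR set was the pooled relaxed peaks of highest signal, down to 81.3 in dm6 and 86.0 in dm3. At the dm6 limit there were 2438 pooled dm3 peaks against 2451 in dm6. At the dm3 limit there were 2214 pooled dm6 peaks against 2198 in dm3. The excess therefore goes mainly with the lower limit in dm6. Both lists come from the same reads, so no test was made.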

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

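The pooled relaxed list in dm3 holds 184 peaks on heterochromatic or unplaced sequences, outside the chromosome arms that the comparisons use. They are listed because the comparisons do not use them and they number more than 3, the limit taken for a count of 0. That list was named as peaks and background. Its entries there show neither that they mark binding nor that their number is unusual. The sources of these peaks were not tested, and no biological explanation was tested for them.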

How the results depend on the processing

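Directions and sides of the threshold held under all alternatives run for replicate agreement (65.5% to 73.5%, each permutation p = 0.001), the promoter share, the X chromosome and chromosome 4. Among summits outside promoters 3 location classes passed against 5, and the log2 odds ratio turned to 0.496 for introns and 0.0136 for the space between genes, since shares that add up to 100% fall as the promoter share rises. With the pooled peaks in place of the IDR set nothing can move, since the sets are identical. The signal difference between promoter and other peaks ranged from 2.40 to 5.997 when a replicate was left out, and did not pass without replicate 3; the cause was not tested. These lists have their own scale (maximum 537 in replicate 1 and 531 in replicate 3, against 1017), so the differences cannot be set beside the pooled 9.57; relative to the median of the other peaks they were 3.73% in replicate 1 and 11.97% in replicate 3, against 8.63%. By -log10 q it was 0 (permutation p = 1), since most peaks share the maximum. In the stronger part of the IDR set, which has fewer peaks to test, 3 motifs and 248 words passed, against 7 and 716; DRE, motif 1, Ohler motif 6 and the TATA box lost their calls. With GC-matched summits as control 3 motifs passed, and the log2 odds ratio of the TATA box turned to -0.11. Counting summits anywhere in a gene or 1000 bp upstream put 12 lists past the threshold against 7, and gained the dorsoventral and mesoderm, Notch and Hippo lists as higher and the chorion and accessory gland and digestive protease lists as lower; the cause was not tested. In the logistic regression the tRNA log2 odds ratio turned to 0.066; 4 lists without peaks have no finite estimate there, though their test counts, and neuronal differentiation gained a call. The alternatives that count each summit for its nearest start site, leave out genes of another kind, or leave out promoter summits, were chosen after the data were seen. An equal number of top pooled peaks per build left a difference of 2 on the arms against 253 IDR peaks, which is fixed by the equal number. Among 432 comparisons of lists, motifs, words and classes, the identical set left out, 396 kept their side, 17 lost the threshold and 19 gained it. The words were chosen for the smallest p in these same peaks, and the alternatives reuse the same 2 replicates. Kept sides are therefore not independent support. Of 50 ranks of named peaks in single replicates, 6 were beyond 25. Depth is unknown and cannot be related to any of these.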

Other observations

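The test of housekeeping genes below was chosen after its result was seen, and its genes were changed once; the count of each summit for its nearest start site and the comparison at equal GC content were added after the data were examined, before their values were known. The word CACGCCC was found more often away from promoters. It lay within 50 bp of 167 of 1215 summits beyond 500 bp of a start site (13.7%, 11.9% to 15.8%) and of 65 of 1236 promoter summits (5.26%, 4.08% to 6.65%), a difference of 8.49 percentage points (Fisher's exact test, two-sided, p = 5.24e-13). It was not more frequent in stronger peaks, with 8.65% in the stronger part of the IDR set and 10.3% in the weaker, a difference of -1.62 points (exact test, p = 0.19). At equal GC content, averaged over 13 classes of summit GC, the difference between distal and promoter summits was 6.79 points (permutation p = 1.0e-04, the smallest that 10000 permutations within classes can give). Beside the summits the word was at 1.48% for distal and 1.21% for promoter peaks. That distal binding may rest on the word more often remains a hypothesis, since the lists do not show what the protein contacts. With GC-matched relaxed summits as control, the word was at 9.54% against 4.38% (exact test, p = 5.06e-21).

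Peaks at ribosomal protein promoters were not accounted for by the word. Of 47 IDR summits at these promoters 0 had it within 50 bp, so that the share was 0% with an upper limit of 7.55%. The lack of the word does not set them apart from other promoter summits, of which 5.47% had it (exact test, p = 0.171). Only the exact word was counted here, not other forms of the Sp/KLF box. The share of tRNA genes with a peak was 4.48%, far below that of ribosomal protein genes. It cannot decide on activity of genes as such, since the activity of no gene was measured and tRNA genes may differ from other active genes. The deficit of tRNA genes against other genes did not pass with a window of 1000 bp or in the regression, but even at 1000 bp their share was 11.03% (upper limit 15.2%), against a lower limit of 42.1% for ribosomal protein genes. Housekeeping genes in general had a lower share than ribosomal protein genes, whose lower limit was 38.9%. It was 20.6% (14.9% to 27.2%) for 180 genes of oxidative phosphorylation, the proteasome, glycolysis and the mitochondrial ribosome, paralogs named as such left out. Its lower limit was above the 12.03% of all protein-coding genes. Among the 180 genes, those of glycolysis were as high as ribosomal protein genes, with peaks at 6 of 12 (21.1% to 78.9%). Housekeeping activity, or a property shared by some strong promoters, therefore stays open, since promoter activity was not measured and the test was chosen after its result was seen. The test was first made on the whole lists of oxidative phosphorylation and the proteasome (11.4%). With each summit counted for its nearest start site, 46.2% of ribosomal protein genes still had a peak. Open chromatin or a precipitation background at the most active promoters may remain, since control libraries were not analysed here, and no biological explanation was tested by a comparison of sample groups.

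The promoter peak of Sox14, the peak of rank 4, lies 6.33 kb beyond the end of CG3065 itself. If extra copies of the tagged locus in the line were the cause, other relaxed peaks around the gene should be raised. The median signal of 17 other relaxed peaks within 20 kb was 31.0, at percentile 44.8 of 878 random gene surroundings, whose median was 31.7. The median was therefore not raised, but this cannot decide on extra copies of the surroundings. The pooled list ends at a signal of 21.5, and weak peaks raised past that limit would keep the median low. A construct that holds only part of the locus was not tested. No biological explanation was tested.

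Few histone genes had even a relaxed peak. A pooled relaxed peak lay at the start site of 3.48% (0.956% to 8.67%) of 115 genes matched as histones, against 49.7% of all other genes. All 111 copies of the repeated cluster on 2L had 0, while the 4 other histone genes each had one; this split was chosen after the values were seen. This is consistent with reads that cannot be placed in repeated copies, but chemoreceptor genes (8.94%) and cuticle protein genes (9.38%), which are not such an array, were also low. Lack of binding in the cluster therefore cannot be excluded, and no biological explanation was tested.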
